A study of Mus musculus with 208 samples.

How the data were processed

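RNA of the striatum was taken with the miRNeasy kit, polyadenylated RNA was sequenced on Illumina HiSeq instruments, and the submitters' processing notes name CASAVA 1.8.2 for the reads. The aligner and the genome build are not given in the sources used here. The deposited values are of 2 kinds for the same libraries and 39179 Ensembl gene IDs. The authors' expected counts, estimated read counts per gene, are fractional, with 32.7% of the values above 0 not whole numbers, and they were rounded for the count models. The authors' second matrix holds FPKM, fragments per kilobase of exon scaled to the mapped fragments, which already allow for depth and gene length. A gene symbol was given for 37607 of the IDs (96.0%), which hold 99.7% of the counts. Total counts per library ran from 29.1 to 49.6 M (M, 1e+06 counts) with a median of 35.7 M, and error bars on counts cover sampling between animals and not the counting of PCR copies as separate molecules.

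Libraries were grouped by line, age and the line with which wild types were housed, in 26 groups of 8. Each age was fitted on its own with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17006 genes at 2 months, 17642 at 6 months and 17170 at 10 months. Libraries were scaled by TMM factors. A quasi-likelihood negative binomial model with a trended dispersion, robust moderation, 1 term per group and sex as a covariate was fitted. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each test. The standard error of a log2 fold change was taken as its size over the square root of F. Tests were each line against Q20 at each age (15), each line against its own wild-type cage mates at 6 months, Q20 against wild type at each age, a linear trend over the 6 lines in log2 change per 10 CAG repeats at each age, the difference of the Q175 effect between sexes at each age and between ages, and any difference among the 6 wild-type groups of 6 months. In all there were 32 such tests. Levels are CPM, counts per 1e+06 counts of the TMM-scaled library, with the SD of 8 libraries, except for the count ranges per library of single regulators, which are counts.

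The genes named follow a rule set before the data were examined, as were the groups, tests, gene lists and most alternatives. The rule takes Htt, then for Q175 against Q20 at each age and for the trend at 6 months the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM over the libraries of that age. It takes 3 of each in the other line and trend tests, and the 5 smallest p in the tests of sex, age and housing. Symbols of predicted genes and clones were left out and list members were added. Gm2420 and the count ranges of Wt1, Onecut1, Hoxc4, Hoxc5 and Pou4f1 fall outside the rule and were chosen after their values were seen.

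There were 29 gene lists of cell types, pathways and gene families, each counted by its members past the threshold over all genes and when adjusted over the list alone. They were tested with camera from limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the 29 lists, and again with a correlation estimated from the libraries. Scores of the cortical, thalamic and choroid plexus lists per library are means of standardised log2 CPM, with a prior count of 1. Changes of lines and ages were compared across genes by Pearson and Spearman correlation. Gene lengths and the distance from Htt came from the GENCODE M21 annotation (GRCm38), in a window of 10 Mb, and no coordinates are given because the authors' build may be another. Figures were drawn with matplotlib 3.10.9.

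The alternatives set before the data were examined were the DESeq2 1.42.0 Wald test, RLE factors, no filter on low counts, a minimum absolute log2 fold change of 0.3, limma-trend on log2(FPKM + 1) for genes with at least 1 FPKM in 8 libraries, the replicate number as a block, the L code in the library names as a further covariate, only the groups compared in the fit, wild types as the reference, the rank of the line in place of repeat length, Q20 or Q175 left out of the trend, called genes only for the correlations and the estimated correlation for the lists. Chosen after the data were seen were fits without the 7 libraries with a median correlation under 0.97, without the library lacking Y-linked counts, with the 3 tissue scores as covariates, with the difference of Q20 from its own cage mates taken off, and without single libraries that held most of the counts of a named gene or the highest tissue score. For each test the labels were also shuffled within sex in 100 splits, or 50 for the age tests, with the dispersion trend of the real grouping kept.

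The pipeline was tested on simulated data made from the library depths and dispersions found here, with changes of a known size put into single genes and a list. The groups hold different animals that share only a replicate number, so no paired test was used. No library was left out of the main results. The counts of the normal and the expanded Htt allele were not separated, reads were not used here, and no coordinates are reported.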

Results

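Polyadenylated RNA of the striatum was sequenced from heterozygous Huntington disease knock-in mice on the C57BL/6 background and from wild types. The striatum is the brain region whose medium spiny projection neurons are lost early in the human disease, which is caused by a long CAG repeat in the huntingtin gene, Htt. Each knock-in line carries 1 altered Htt allele and is named after its repeat length: Q20, with a repeat in the normal human range, Q80, Q92, Q111, Q140 and Q175. The libraries form 26 groups of 8 at 3 ages, with 56 libraries at 2 months, 96 at 6 months and 56 at 10 months. There were 18 knock-in groups with 144 libraries and 8 wild-type groups with 64. At 6 months each line had wild types from its own cages, and at 2 and 10 months the wild types were housed with Q20. Sexes were 4 and 4 in each group, except for 3 females and 5 males in Q80 at 2 months and 5 females and 3 males in Q20 at 10 months. Total counts per library ran from 29.1 to 49.6 M, with medians of 31.9 M at 2 months, 41.0 M at 6 months and 33.0 M at 10 months. Between 19886 and 21587 genes had a count in a library.

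At 2 months 7 libraries stood apart from the rest of their age, with a median correlation under 0.97 with the other libraries and 17.2 to 24.1% of counts on mitochondrial genes, against 11.4 to 14.9% in the 49 others. They were Q20 M2 and M3, Q80 M5, Q92 M3 and M4, Q111 F2 and wild type F1, where F and M give the sex and the digit the replicate. None of the 7 was a Q140 or Q175 library. At 6 and 10 months the lowest median correlation was 0.979 and 0.984. One library labelled male, Q80 M3 at 2 months, had 14 counts of Xist, the X-inactivation RNA that male libraries have at 11 to 110 counts, and 0 counts on each of the 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Its X-linked genes Eif2s3x (104 CPM) and Kdm6a (35.6 CPM) lay near the male means (102 and 32.1) and below the female means (157 and 46.5). Its name carries the code of the female Q80 libraries of that age and not that of the other males. The sex chromosomes of the animal were not tested. Every other library matched its sex label.

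**Figure D1:**
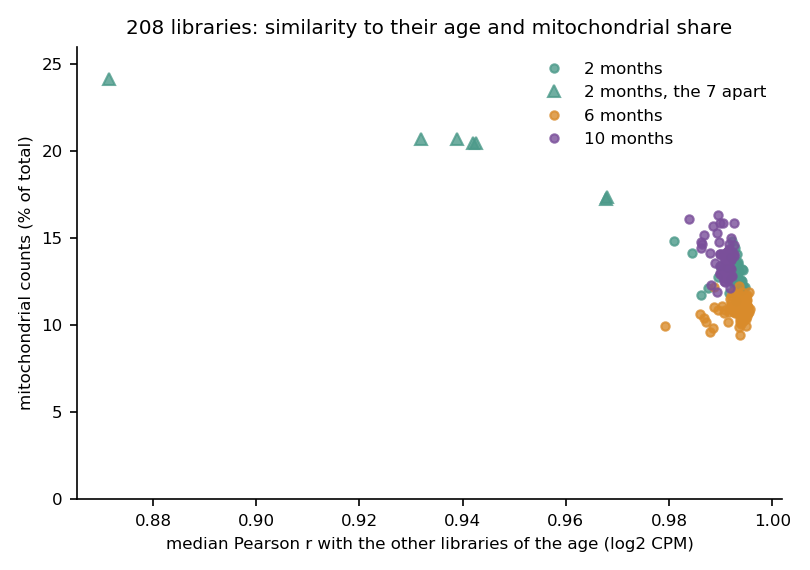
Each point is 1 library, placed by its median Pearson correlation of log2 CPM with the other libraries of its age and by its percentage of counts on mitochondrial genes. The 7 libraries set apart at 2 months lie between 17.2 and 24.1% mitochondrial counts, and the 49 others of that age between 11.4 and 14.9%.

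The first question was how a long repeat changes striatal expression against the short repeat of Q20, by line and age. At 6 months the genes that set medium spiny neurons apart were lower in Q175 than in Q20. Of 24 genes enriched in these neurons, 23 fell and 1, Tmem158, did not pass the test. The largest fall among them was in Scn4b, a sodium channel beta subunit, with a log2 fold change of -1.46 (SE 0.0678, n = 8 and 8), from 1872 to 681 CPM. Cnr1, the cannabinoid receptor, fell by 1.15 on the log2 scale, Pde10a, a striatal phosphodiesterase, by 0.99, and Ppp1r1b, the dopamine signalling protein DARPP-32, by 0.82. The markers of D2-type neurons, which form the indirect pathway, followed, with 4 of 5 lower: Penk, the enkephalin precursor, fell by 1.23 (SE 0.0721), Adora2a, the adenosine A2a receptor, by 0.94 and Drd2, the dopamine D2 receptor, by 0.72. Among 7 markers of D1-type neurons, which form the direct pathway, 4 fell and 2 rose. Chrm4, a muscarinic receptor, fell by 0.89 and Drd1, the dopamine D1 receptor, by 0.85, while Isl1, a transcription factor of these neurons, rose by 0.23 and Eya1 by 0.32. For every gene of these 3 lists that passed, all 8 Q175 libraries lay beyond the Q20 mean. Adjusted over the list alone, 23, 4 and 4 genes were lower. The medians of the 3 lists were -0.62, -0.75 and -0.21. The list test (camera) gave an adjusted p of 3.2e-29 for the medium spiny neuron genes, 9.11e-07 for the D2-type and 0.105 for the D1-type markers. With an estimated correlation between genes, adjusted p = 0.0521 for each of the first pair.

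Other groups of genes moved at the same age. Of 18 immediate early genes, which neurons switch on after activity, 12 fell and none rose, with Egr2 at -2.11 (SE 0.363), Npas4 at -0.99, Egr1 at -0.93 and Arc at -0.91 (median -0.73, adjusted p = 0.000894, adjusted p = 0.633 with an estimated correlation). Of 24 clustered protocadherin genes, which encode cell surface labels of single neurons, 16 rose and 1 fell. Pcdhb2 and Pcdhb3 each rose by 0.75, Pcdhb21 rose by 0.69 and Pcdhb9 by 0.59, while Pcdhb8 fell by 0.54 (median 0.31, adjusted p = 2.3e-08, adjusted p = 0.0521 with an estimated correlation). Endothelial and mural markers were lower in 9 of 12 genes, 10 when adjusted over the list alone, among them the endothelial adhesion molecule Pecam1 (-0.25) and the efflux pump Abcb1a (-0.21) (median -0.20, adjusted p = 0.00141, adjusted p = 0.395 with an estimated correlation). Of 81 potassium channel genes 27 fell and 7 rose, with Kcnh4 at -1.08, Kcnab1 at -0.66 and Kcng1, a silent subunit, at 0.56. The median of that list was -0.03 (adjusted p = 0.026, adjusted p = 0.395 with an estimated correlation) and turned to 0.03 on the FPKM scale, on which the median of all genes lay at 0.05. Of 35 glutamate and GABA-A receptor subunits 14 fell, as Gabrd (-0.71) and Grik2 (-0.69), and 8 rose, a list that did not pass (adjusted p = 0.0583). Adjusted over the list alone, 12 immediate early, 16 and 1 protocadherin, 27 and 7 potassium channel and 14 and 8 receptor genes passed. With wild types as the reference 8 of the 29 list tests passed at this age, against 6 with Q20 as the reference.

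Other large changes of Q175 at 6 months lay outside these lists, among genes with a mean of at least 1 CPM over the age. Dsp, the desmosomal plaque protein desmoplakin, rose by 1.98 (SE 0.384) from 0.826 to 3.34 CPM, and Sfmbt2, a Polycomb group gene, by 1.63 (SE 0.0869). Adamts19 rose from 0.494 to 1.75 CPM. Irs4, an insulin receptor substrate, rose by 1.35, Acy3, an aminoacylase, by 1.32, AW551984 by 1.24, Slitrk6 by 1.13, Kazald1 by 1.11 and Slc45a3 by 1.10. Abhd12b rose by 3.29 (SE 1.32) with 6 of 8 libraries above the Q20 mean. Onecut1, a homeobox gene of the developmental list with a lower mean over the age, rose by 5.02 (SE 0.377), from 0.073 to 2.45 CPM. The falls included Wnt8b, a Wnt ligand, at -2.74 (SE 0.247), Gpx6, a glutathione peroxidase, at -2.71 (SE 0.16) from 7.49 to 1.17 CPM, Tmprss6 at -2.16, Mafa at -2.12, Vwa7 at -2.07, Abhd11os at -2.03 and Slc4a11 at -1.91. All 8 Q175 libraries were on the stated side of the Q20 mean for the genes other than Abhd12b. The pituitary hormone genes Gh (-5.40) and Prl (-5.05) also passed, but the single library Q20 M4 held 98.6% and 93.5% of their Q20 counts, and without it they stood at 0.60 and 0.10 and did not pass. Abhd12b stood at 3.15 without Q20 M4 and did not pass (adjusted p = 0.069). In all 6382 of 17642 genes passed, 3179 higher and 3203 lower, with a median absolute log2 change of 0.21.

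**Figure D2:**
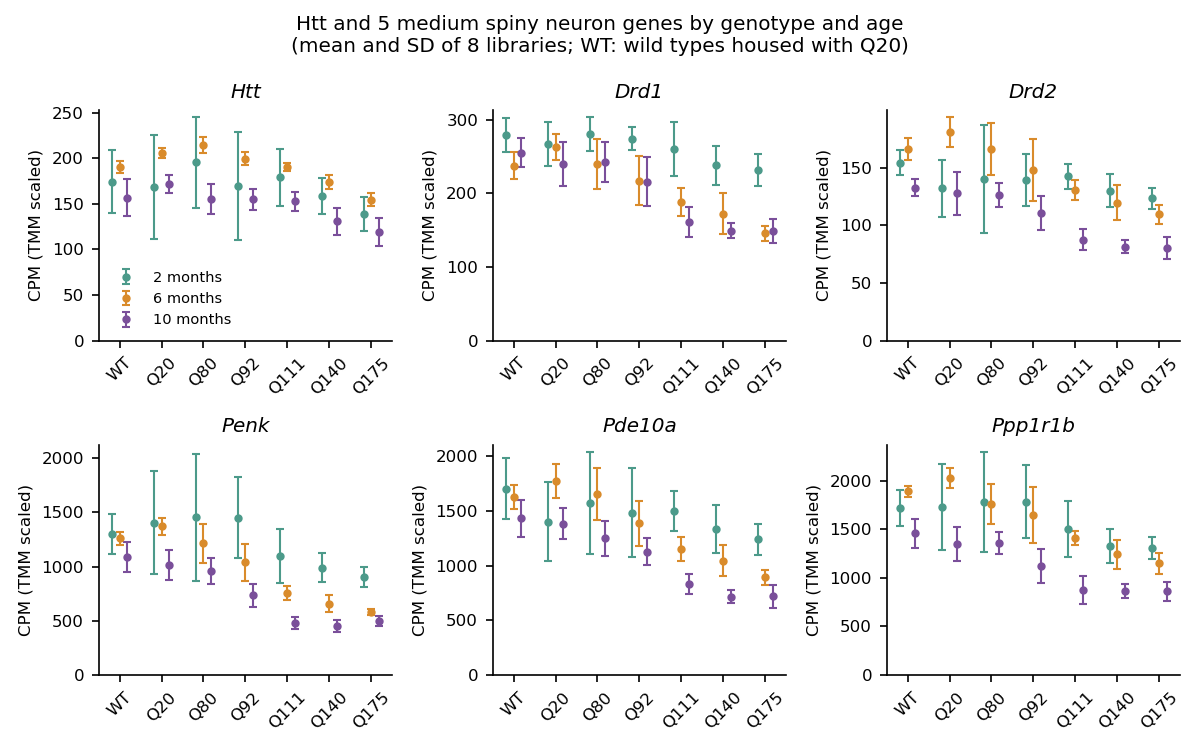
Points and bars give the mean and SD of 8 libraries in TMM-scaled CPM for Htt and 5 medium spiny neuron genes, by genotype and age. Penk falls from 1371 CPM in Q20 to 583 CPM in Q175 at 6 months.

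Lines with shorter repeats had fewer called genes at 6 months. In Q140 4925 genes passed (2434 higher, 2491 lower) and in Q111 2261 (947 and 1314). The 24 medium spiny neuron genes had 23 members lower in Q140 (median -0.47) and 21 in Q111 (24 adjusted over the list alone, median -0.35). Penk fell by 1.06 in Q140 and by 0.86 in Q111, Pde10a by 0.76 and 0.63, Drd1 by 0.61 and 0.48 and Drd2 by 0.59 and 0.47. Among the clustered protocadherins 18 rose and 1 fell in Q140 (median 0.40, above that of Q175), and 16 rose and none fell in Q111 (0.26). Microglia markers were lower in 10 of 14 genes in Q140 (11 adjusted over the list alone, median -0.14), in 3 in Q175 (1 adjusted over the list alone, -0.050) and in none in Q111. Endothelial and mural markers were lower in 8 of 12 genes in Q140 (median -0.16) and in none in Q111. Of the immediate early genes 9 were lower in Q140 and 3 in Q111. Sfmbt2 rose by 1.43 and Dsp by 1.33 in Q140, and Gpx6 fell by 2.10 in Q140 and by 1.32 in Q111. Mafa (-1.47) and Tmprss6 (-1.44) were the other largest falls of Q111, and Ipcef1 (0.91, 8 of 8 libraries above the Q20 mean), Cplx3 (0.98, 7 of 8) and Rspo2 (1.22, 6 of 8) its largest rises. With wild types as the reference the change of Cplx3 in Q111 turned to a small fall. Adamts19 rose by 1.52 in Q140, and without the library Q20 M4 it stood at 1.42 and did not pass (adjusted p = 0.0814). Gh (-5.69) and Prl (-4.95) passed in Q140, and without Q20 M4 stood at 0.26 and 0.16.

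Q92 differed from Q20 in 1056 genes at 6 months (529 higher and the rest lower), and Q80 in 51 (36 higher, 15 lower). With only the groups compared in the fit edgeR gave 100 and 0 genes, while DESeq2 on all groups gave 1181 and 48. In Q92 18 of the 24 medium spiny neuron genes were lower (22 adjusted over the list alone, median -0.23), with Penk at -0.40, Pde10a at -0.36, Drd2 at -0.29 and Drd1 at -0.28. Beside them 8 of 12 cortical excitatory neuron markers were higher (9 adjusted over the list alone), with a list median of 1.52. Among these the vesicular glutamate transporter Slc17a7 was at 2.09 (SE 0.541, 6 of 8 libraries above the Q20 mean), and outside the list Igfn1 was at 2.70 and Nrn1 at 1.90. The library Q92 F2 had the highest cortical score of its group, and without it fewer genes passed, 483 of them shared, while Igfn1 (0.79), Slc17a7 (1.27) and Nrn1 (1.45) did not pass. With the scores of the cortical, thalamic and choroid plexus lists as covariates 253 genes passed in Q92. The falls Rpl9-ps7 (-0.74), ENSMUSG00000048107 (-0.72) and Sec14l3 (-0.59) had 8 of 8 Q92 libraries below the Q20 mean, and without Q92 F2 ENSMUSG00000048107 stood at -0.68 and did not pass (adjusted p = 0.0561) while the others passed. In Q80 the largest rises were choroid plexus genes: Ttr, the thyroid hormone carrier of the choroid plexus, at 4.94, Slc4a5 at 4.22 and Kcnj13 at 4.08, each with 6 of 8 libraries above the Q20 mean. The library Q80 F3 held 92.5% of the Ttr counts of Q80, and without it Ttr stood at 1.27 and edgeR, the only tool run so, gave 0 genes. Ano2 (-0.54), Map2k6 (-0.24) and Camkk1 (-0.22) were lower in 8 of 8 libraries, and without Q80 F3 they stood at -0.48, -0.23 and -0.19 and did not pass (adjusted p = 0.334, 0.334 and 0.344). The 24 medium spiny neuron genes had 0 members past the threshold in Q80 (median -0.12).

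**Figure D3:**
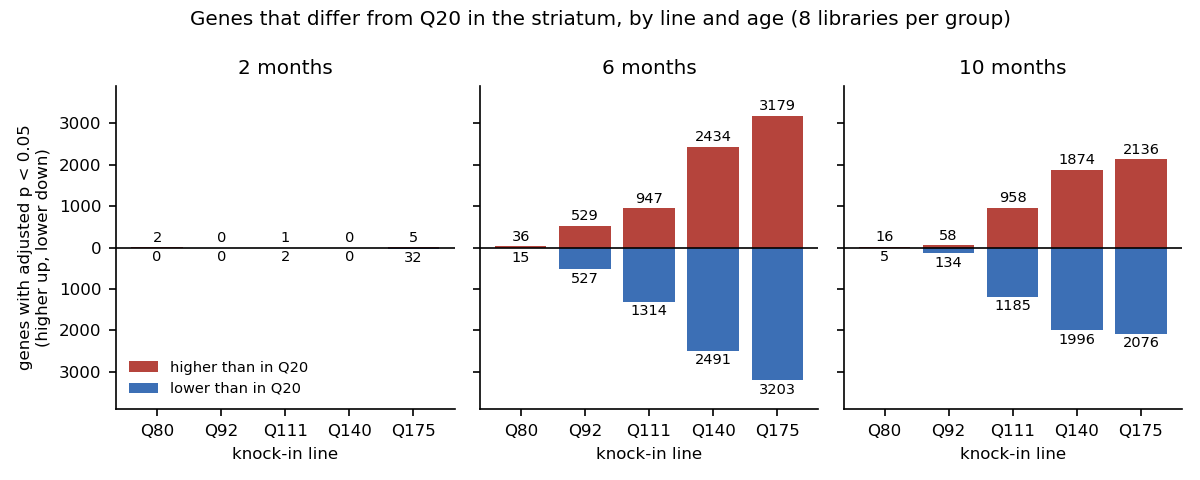
Bars give the number of genes higher (up) and lower (down) than in Q20 with an adjusted p under 0.05, for each line at each age, 8 libraries per group. At 6 months they run from 51 genes in Q80 to 6382 in Q175, and at 2 months from 0 to 37.

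The second question was which genes follow repeat length over the 6 lines, given as log2 change per 10 repeats. The trend test took libraries as independent, though repeat length differs only between the 6 lines. Its SE and adjusted p thus do not measure the spread between lines. Differences between lines or their cohorts from another cause are not told apart from repeat length at any age. At 6 months 6931 genes had a trend (3530 rising, 3401 falling). Sfmbt2 rose by 0.12 per 10 repeats (SE 0.0101), Dsp by 0.12 (SE 0.022), and Adamts19, Acy3, Irs4, AW551984, Rprm, Tnnt2, Slc45a3 and Slitrk6 by 0.092 to 0.074. Gpx6 fell by 0.19 (SE 0.0163), Wnt8b by 0.18, Tmprss6 by 0.16, Mafa by 0.16, Egr2 by 0.15, and Slc4a11, Vwa7 and Abhd11os by 0.14 each. Of the 24 medium spiny neuron genes 23 fell with repeat length, of the protocadherins 18 rose and 1 fell, and of the 18 immediate early genes 15 fell (16 adjusted over the list alone). The trends of Gh (-0.37) and Prl (-0.29) ended without Q20 M4 (0.032 and 0.019), while that of Adamts19 stayed at 0.084 and no longer passed (adjusted p = 0.0566). Without the Q175 libraries 4285 genes had a trend.

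At 2 months the trend with repeat length passed in 60 genes (8 rising, 52 falling). Kcng1 rose by 0.033 per 10 repeats, Pcdh20, a protocadherin outside the clusters, by 0.025 and Htr2c, a serotonin receptor, by 0.024. Tmprss6 fell by 0.081 and Gpx6 by 0.067. Of the 24 medium spiny neuron genes 4 fell (14 adjusted over the list alone), and Penk fell by 0.048 (adjusted p = 0.0198). Pomc (-0.12), the precursor of melanocortins and beta-endorphin, passed with 73.4% of its Q20 counts in the library Q20 F4. Without Q20 F4 it stood at -0.021 and did not pass, and 100 genes had a trend, 59 of them shared. Without the 7 libraries set apart 255 genes had a trend, 55 of them shared. Without the Q175 libraries edgeR gave 0 genes with a trend, and it was the only tool run for trends. At 10 months the trend passed in 5608 genes (2725 rising, 2883 falling), led by Wt1 (0.44 per 10 repeats, SE 0.0351), Onecut1 (0.39) and Crnde (0.19) upward and by Gpx6 (-0.24), Wnt8b (-0.22) and Slc4a11 (-0.18) downward. There 23 of the 24 medium spiny neuron genes fell, and 18 protocadherins rose and 1 fell. Of 12 interferon-stimulated genes 6 rose (10 adjusted over the list alone). Against Q20 at 10 months the medians of that list were -0.031 in Q80, -0.10 in Q92, -0.18 in Q111 and -0.099 in Q140. No member passed in these lines. The list thus lay above Q20 in Q175 alone and did not rise step by step with repeat length.

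The mutated gene itself was lower with the longest repeats. Htt in Q175 was 0.41 below Q20 at 6 months on the log2 scale (-0.41, SE 0.0256, adjusted p = 6.27e-25). At 10 months the change was -0.52 (adjusted p = 2.98e-07), at 119 ± 15.7 against 171 ± 9.87 CPM. At 2 months it was -0.27 and did not pass (adjusted p = 0.832) with the Q20 libraries M2 and M3, both among the 7 set apart, in the fit. In Q140 Htt fell by 0.24 at 6 months and by 0.39 at 10 months, and in Q111 by 0.11 at 6 months. Its trend per 10 repeats was -0.029 at 6 months (adjusted p = 1.71e-11), -0.035 at 10 months (adjusted p = 9.65e-09) and -0.019 at 2 months (adjusted p = 0.549). Against their own wild-type cage mates Q175 (-0.36) and Q140 (-0.17) were lower and Q80 (0.15, adjusted p = 0.000143) was higher, while Q111 stood at -0.01 (adjusted p = 0.866) and Q92 at 0.10 (adjusted p = 0.134). Counts from the normal and the expanded allele were not separated.

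At 2 months few genes differed between Q175 and Q20: 37 of 17006 passed, 5 higher and 32 lower. The median SE of a log2 change was 0.114 there against 0.060 at 6 months. Changes of a given size were thus harder to find at 2 months, and the counts of the ages do not compare directly. Under the alternatives set before the data were examined the count ran from 11 with only the groups compared in the fit to 65 with DESeq2 and 79 with wild types as the reference. Kcng1 rose most surely, by 0.50 (SE 0.067) from 28.7 to 40.5 CPM, followed by Klhl1 (0.34), Armcx6 (0.27) and Cntn6, a neuronal contactin (0.20). The falls were led by Tmprss6 (-1.30, SE 0.237), Gpx6 (-0.95), Wnt4 (-0.84), Plk5 (-0.75), Dgat2l6 (-0.75), Krt9 (-0.69), Slc4a11 (-0.61), Odf4 (-0.60), Ddit4l (-0.59) and Mas1 (-0.57). Each of these genes had 8 of 8 Q175 libraries on the stated side of the Q20 mean. Cnr1 (-0.34) among the medium spiny neuron genes and Adora2a (-0.34) among the D2-type markers were lower, and Penk was at -0.63 (adjusted p = 0.0766). Adjusted over the lists alone 7 of 24 and 3 of 5 genes were lower. The medians of these lists were -0.18 (adjusted p = 5.92e-12, adjusted p = 0.104 with an estimated correlation) and -0.34 (adjusted p = 4.07e-05, adjusted p = 0.0697 with an estimated correlation). The protocadherin median was 0.21 (adjusted p = 5.92e-12, adjusted p = 0.104 with an estimated correlation) with 0 members past the threshold and 1 when adjusted over the list alone, and it was 0.095 without the 7 libraries (adjusted p = 0.00117).

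Several lists at 2 months turned with the libraries set apart, which include Q20 M2 and M3. Ribosomal protein genes had a median of -0.18 in Q175 with all libraries and 0.11 without the 7. Respiratory chain subunits had -0.22 with them and 0.092 without, and proteasome subunits -0.10 and 0.066. The list tests passed both ways, as lower with all libraries (adjusted p = 4.07e-05, 4.15e-07 and 0.000814) and as higher without the 7 (1.61e-16, 1.98e-13 and 3.07e-06), while with an estimated correlation adjusted p = 0.813 for each. Oligodendrocyte and myelin genes (median -0.19, adjusted p = 8.23e-05, adjusted p = 0.687 with an estimated correlation) and immediate early genes (-0.20, adjusted p = 0.0224, adjusted p = 0.813 with an estimated correlation) stood at -0.075 (adjusted p = 0.0434) and -0.087 (adjusted p = 0.31) without the 7, so only the former passed. With wild types as the reference none of these 5 lists passed (adjusted p = 0.922, 0.991, 0.946, 0.232 and 0.232), while cortical neuron markers (adjusted p = 0.00075), interferon-stimulated genes (adjusted p = 0.00057) and chaperones (adjusted p = 0.0197) passed as higher. Other lists passed against Q20 without the 7 and not with all libraries. Glutamate and GABA-A receptor subunits went from 0.019 (adjusted p = 0.522) to -0.072 (adjusted p = 0.0021) and potassium channel genes from -0.015 (adjusted p = 0.902) to -0.083 (adjusted p = 0.0044). Autophagy genes went from -0.039 (adjusted p = 0.246) to 0.053 (adjusted p = 0.0044) and chaperones from 0.002 (adjusted p = 0.808) to 0.073 (adjusted p = 0.00562). The correlation was estimated with all libraries only. Without the 7 the medium spiny neuron genes had a median of -0.11 with 5 of 24 lower (10 adjusted over the list alone), and the D2-type markers -0.22. Without the 7 libraries 84 genes passed in Q175, 30 of them among the 37.

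The other lines gave almost no calls at 2 months. In Q111 3 genes passed, with Crhbp (-0.91), a binding protein of corticotropin-releasing hormone, and Tcfl5 (-0.80) lower, and without the 7 libraries 0 genes. In Q80 2 genes passed, of which the pseudogene Atp6v0c-ps2 (4.87) had 98.1% of its Q80 counts in Q80 M5, one of the 7, and 2 of 8 libraries above the Q20 mean. Without the 7 libraries 1 gene passed in Q80. In Q92 edgeR gave 0 genes, with 216 at an unadjusted p under 0.05, and DESeq2 and limma gave 0 too. In Q140 edgeR gave 0 genes, with 7.8e+02 (2 digits) at an unadjusted p under 0.05, DESeq2 11, limma 4 and edgeR without the 7 libraries 2.

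At 10 months the striatal neuron genes were again lower in Q175, and 9 of 23 homeobox and other developmental transcription factor genes were higher. Of the 24 medium spiny neuron genes 23 fell, Scn4b by 1.32 (SE 0.0815) and Cnr1 by 1.08 (median -0.52, adjusted p = 5.35e-27, adjusted p = 0.0454 with an estimated correlation). Of the D2-type markers 4 of 5 fell, Penk by 1.04 and Adora2a by 0.82 (median -0.69, adjusted p = 6.85e-07, adjusted p = 0.0454 with an estimated correlation). Of the D1-type markers 3 fell, Drd1 by 0.69, and Eya1 rose by 0.27 (median -0.091, adjusted p = 0.0475, adjusted p = 0.539 with an estimated correlation). Wt1, the Wilms tumour transcription factor, rose by 5.75 (SE 0.273), from 0 to 8 counts per library in Q20 to 122 to 215 in Q175. Onecut1, a homeobox gene of liver and pancreas, rose by 4.65 (SE 0.28), from 0 to 9 counts to 48 to 214. Hoxc4 had 57 to 200 counts in each Q175 library and 2 counts in all 8 Q20 libraries together, and Hoxc5 33 to 108 counts against 1 count. Of 23 homeobox and other developmental transcription factor genes 9 rose and none fell (10 rose and 1 fell adjusted over the list alone), with Pax6 at 0.46 and Twist1 at 1.49 (list median 0.25, adjusted p = 0.000271, adjusted p = 0.0397 with an estimated correlation). The filter on low counts kept 15 members of this list at 2 months, 20 at 6 months and 23 at 10 months. Members almost absent in Q20, as Hoxc4 and Hoxc5, pass it only through groups where they are higher. They could hardly fall, so the lack of falls, the median and the list test lean upward by the filter.

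Counts of these regulators in other lines and at other ages were looked up after the calls had been seen. At 10 months Hoxc4 had 1 to 10 counts per library in Q111 and 16 to 44 in Q140, and 0 to 1 in Q80, a range within that of Q20. Wt1 had 47 to 128 counts per library in Q111 and 104 to 183 in Q140. At 6 months Q175 had 59 to 160 counts of Wt1 and 61 to 158 of Onecut1 against 0 to 6 of each in Q20, and 4 to 37 of Hoxc4. At 2 months Q175 had 1 to 7 counts of Wt1 and 0 to 1 of Hoxc4, against 0 to 2 of each in Q20. Pou4f1, a sensory neuron transcription factor, had 4 to 27 counts in Q175 and 0 to 5 in Q20 at 10 months.

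At 10 months 7 of 12 glial reactivity and cytokine genes rose in Q175 and none fell (8 adjusted over the list alone), with Serpina3n, a marker of reactive astrocytes, at 1.05 (SE 0.0975), the intermediate filament Vim at 0.45 and the class I molecule H2-D1 at 0.36 (median 0.28, adjusted p = 0.00015, adjusted p = 0.0397 with an estimated correlation). Of 12 interferon-stimulated genes 9 rose (12 adjusted over the list alone), with Usp18 at 0.78 (median 0.59, adjusted p = 0.00015, adjusted p = 0.309 with an estimated correlation). In Q20 against wild type at that age the interferon list had a median of -0.21 (SE 0.0487), with 0 members past the threshold. Part of its rise in Q175 is thus not told apart from a lower level in Q20. For Irf7 8 of 8 Q175 libraries were above the Q20 mean, for Usp18 6 and for Oasl2 (0.58) 5. Gfap, the astrocyte filament, rose by 0.48, while the glutamate transporter Slc1a2 fell by 0.38. Astrocyte markers as a list, with 2 genes higher and 6 lower of 12, did not pass (adjusted p = 0.0575). Microglia markers had 1 of 14 genes lower, with a median of 0.021 and a test pointing down (adjusted p = 0.986). Clec7a, a pattern recognition receptor of myeloid cells, rose by 1.41 (SE 0.143). The next shorter lines did not share the rise of the glial reactivity list at 10 months. In Q140 2 of its 12 genes rose and 2 fell (median 0.037), and in Q111 0 passed (median -0.041). Gfap stood at -0.21 in Q140 (adjusted p = 0.145) and -0.19 in Q111 (adjusted p = 0.278).

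Of 34 glutamate and GABA-A receptor subunits 14 fell and none rose in Q175 at that age (15 adjusted over the list alone), with Grik2 at -0.68, Grm3 at -0.58 and Gabrd at -0.56 (median -0.16, adjusted p = 1.71e-05, adjusted p = 0.0483 with an estimated correlation). Of 79 potassium channel genes 21 fell (22 adjusted over the list alone) and 3 rose (median -0.11, adjusted p = 7.4e-05, adjusted p = 0.0454 with an estimated correlation). Of the clustered protocadherins 14 rose and 1 fell (16 and 1 adjusted over the list alone), with Pcdhb3 at 0.86 (median 0.34, adjusted p = 3.3e-08, adjusted p = 0.0454 with an estimated correlation). Proteasome subunits rose in 13 of 38 genes (18 adjusted over the list alone), with Psmb10 at 0.30 and Psmd1 at 0.17 (median 0.097, adjusted p = 2.7e-06, adjusted p = 0.372 with an estimated correlation). Respiratory chain subunits rose in 8 and fell in 1 of 79 (median 0.080, adjusted p = 0.000876, adjusted p = 0.781 with an estimated correlation). Endothelial and mural markers fell in 6 of 12 genes (7 adjusted over the list alone; adjusted p = 0.00236, adjusted p = 0.287 with an estimated correlation) and interneuron markers in 5 of 10, with Nos1 at -0.38 and Chat at -0.29 (adjusted p = 0.0154, adjusted p = 0.261 with an estimated correlation). Autophagy genes rose in 2 of 14 (adjusted p = 0.0131, adjusted p = 0.372 with an estimated correlation), and immediate early genes fell in 2 of 18 (median -0.11), without passing. With wild types as the reference the test of the respiratory chain pointed down (adjusted p = 0.915), and the interneuron markers (adjusted p = 0.0692) and autophagy genes (adjusted p = 0.158) did not pass.

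Outside the lists the long non-coding RNA Crnde rose by 2.46, Cldn14 by 1.75, Dsp by 1.57, Emx2os by 1.53, Sfmbt2 by 1.40, Acy3 by 1.40 and Ccdc166 by 1.26 in Q175 at 10 months. Wnt8b fell by 3.06 (SE 0.297) and Gpx6 fell by 3.05 (SE 0.199) from 9.45 to 1.10 CPM. Slc4a11 fell by 2.33, Sec14l3 by 2.17, Abhd11os by 2.13 and the calcium release channel Ryr1 by 2.12 (SE 0.122) from 81.8 to 18.9 CPM. Vwa7 fell by 2.07, Tmprss6 by 2.03, Odf4 by 2.00 and Dgat2l6 by 1.76. In all 4212 of 17170 genes passed, 2136 higher and 2076 lower.

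**Figure D4:**
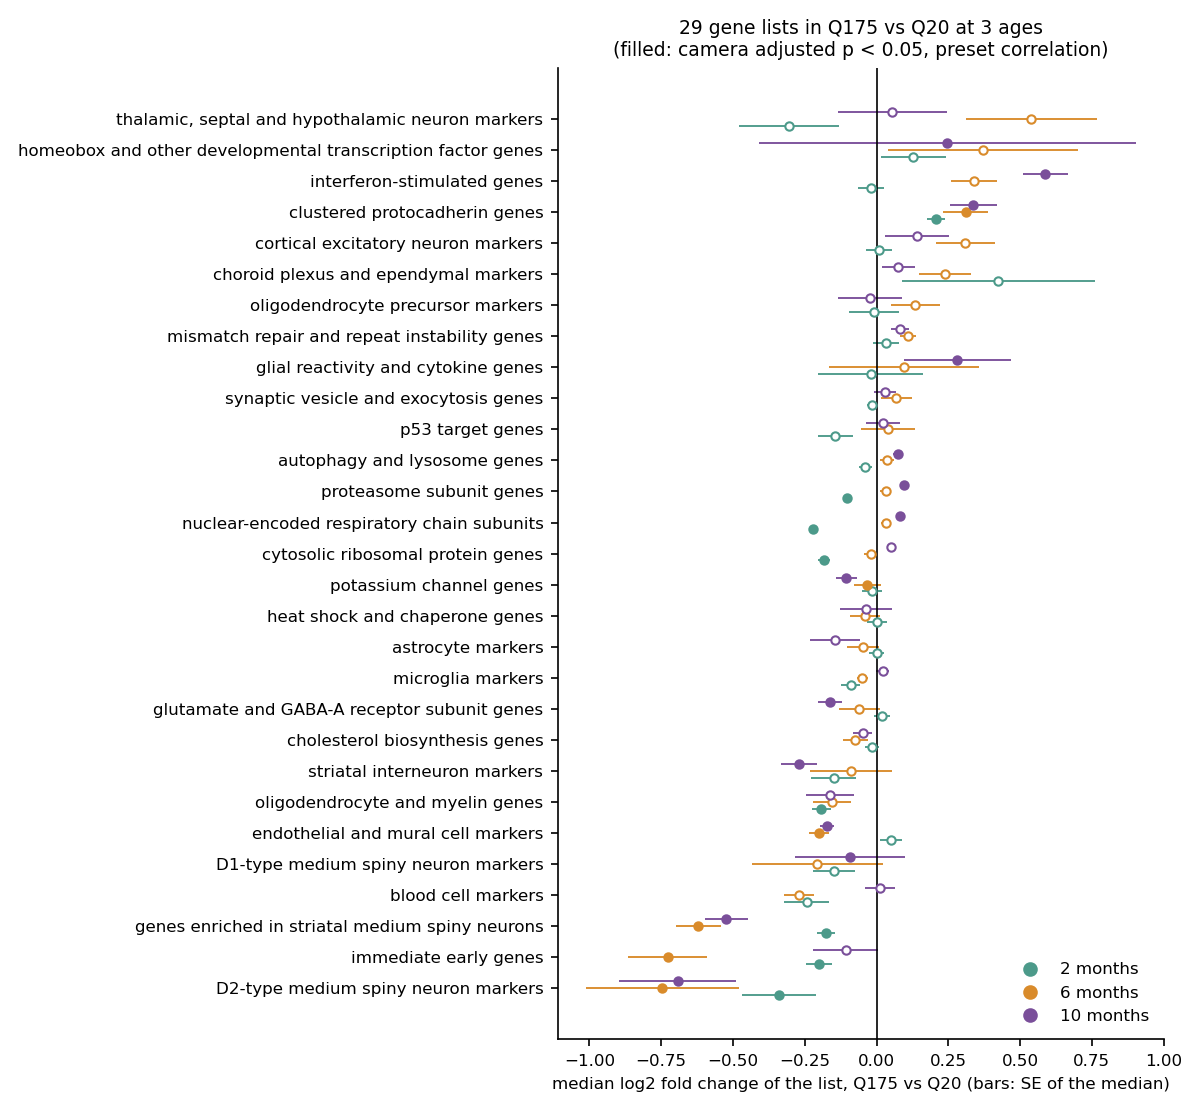
Points give the median log2 fold change of 29 gene lists in Q175 against Q20 at 3 ages with all libraries, with the SE of the median as bars, filled where the camera adjusted p was under 0.05 with the preset correlation. The medium spiny neuron genes lie at -0.18, -0.62 and -0.52 and the clustered protocadherins at 0.21, 0.31 and 0.34 at 2, 6 and 10 months.

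At 10 months Q140 differed from Q20 in 3870 genes (1874 higher, 1996 lower), Q111 in 2143 (958 and 1185), Q92 in 192 (58 and 134) and Q80 in 21 (16 and 5). Of the 24 medium spiny neuron genes 23 fell in Q140 (median -0.47), 18 in Q111 (23 adjusted over the list alone, median -0.39) and 5 in Q92 (9 adjusted over the list alone, median -0.12), and none passed in Q80 (median 0.02). Wt1 rose by 5.52 in Q140, 4.50 in Q111 and 1.66 in Q92, and Onecut1 by 4.26 in Q140 and 3.07 in Q111. Gpx6 fell by 3.15 in Q140, by 2.61 in Q111 and by 1.13 in Q92. Wnt8b was at -2.72 in Q140 and -2.40 in Q111, Sec14l3 at -2.49 in Q140, and Slc4a11 at -1.98 in Q111 and -0.94 in Q92. Crnde rose by 2.19 in Q140, Dsp by 1.39 in Q111, and Dsg1c, a desmosomal cadherin, by 0.77 and AW495222 by 0.55 in Q92. Of the clustered protocadherins 16 rose and 1 fell in Q140, 16 rose in Q111 and 5 rose in Q92. Microglia markers were lower in 5 of 14 genes in Q140 (6 adjusted over the list alone, median -0.13). In Q80 Nptx2, a neuronal pentraxin, rose by 0.51, Ly6c1 by 0.43 and Kcng1 by 0.37, while Tmem245 (-0.23), Tbc1d24 (-0.21) and Tgfbr1 (-0.20) fell. Adjusted over the list alone 62 of 79 respiratory chain subunits (median 0.17), 31 of 81 ribosomal protein genes (median 0.13) and 5 of 5 blood cell markers (median 0.49) were higher in Q80, none of them past the threshold over all genes. In Q20 against wild type at that age the same lists had medians of -0.083, -0.041 and -0.40. Of the blood cell markers 5 of 5 were lower there when adjusted over the list alone. The rise in Q80 is thus not told apart from a lower level in Q20. The count of Q80 depended on the tool and the covariates, from 0 with only the groups compared in the fit to 353 with DESeq2 and 1172 with the L code of the library names as a covariate. That of Q92 also moved. It was lower with only the groups compared or with the L code, and higher with wild types as the reference or with tissue scores as covariates.

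The third question was whether the lines differ from wild types raised in the same cages, which was open to 6 months. Against its cage mates Q175 had 5612 genes (2764 higher, 2848 lower), Q140 4263 (2196 and 2067), Q111 1577 (755 and 822), Q92 9 (3 and 6) and Q80 9 (4 and 5). Of the 24 medium spiny neuron genes all 24 fell in Q175 (median -0.60), 22 in Q140 (-0.41), 14 in Q111 (15 adjusted over the list alone, -0.23) and none in Q92 (4 adjusted over the list alone, -0.10). In Q92 Penk stood at -0.29, Pde10a at -0.22, Drd2 at -0.15 and Drd1 at -0.12, none past the threshold. Of the clustered protocadherins 16 rose and 1 fell in Q175, 19 rose in Q140 and 18 in Q111. Sfmbt2 rose by 1.63 in Q175 and 1.42 in Q140, Dsp by 1.85 and 1.44, and Gpx6 fell by 2.75 and 2.05. Wnt8b was at -2.66 in Q175, and Mafa at -2.22 in Q175, -1.78 in Q140 and -1.62 in Q111, where Tnnt2 rose by 0.80. The interferon-stimulated genes had 4 of 12 members lower in Q140 (8 adjusted over the list alone, median -0.45), against none and a median of -0.086 in Q140 against Q20. The immediate early genes had 5 lower in Q175 (8 adjusted over the list alone) and 4 in Q140.

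Several calls against cage mates were lost without 1 library, some with their change and some with the change kept. In Q111 Prl was at 6.24 with 3 of 8 libraries above the cage mates' mean, and without Q111 F1 it stood at 2.92 (adjusted p = 0.605) and 1284 genes passed. Grid2ip (-1.86) and Tcf7l2 (-1.42) stood at -1.80 and -1.38 without Q111 F1 and did not pass (adjusted p = 0.0588 and 0.0746). In Q140 Prl was at -5.09, and at 1.27 without the wild type F2. In Q92 Pomc was at -3.05, and at -0.02 without the wild type M4, which held 90.6% of the wild-type counts. Krt9 (-0.41) and Ptprv (-0.37) were lower in Q92, and without the library Q92 F2 they stood at -0.36 and -0.33 and did not pass (adjusted p = 0.0563 and 0.125), while 7 genes passed. In Q80 Il1a (-2.24), Atf3 (-1.77) and Ccn1 (-1.21), genes of inflammation and acute stress, stood at -0.11, -0.19 and -0.07 without the wild type M3, and 5 genes passed. Without Q80 F3 or without the wild type M2, the pair of libraries with the highest choroid plexus scores, 41 and 58 genes passed in Q80.

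Abhd1, Dpysl5, Atraid and the predicted gene Gm2420 passed against cage mates in every line. Abhd1 was at 1.37 in Q80, 1.15 in Q92 (7 of 8 libraries above the cage mates' mean), 1.25 in Q111, 1.33 in Q140 and 1.34 in Q175 (7 of 8). Dpysl5, a dihydropyrimidinase-like protein of developing neurons, rose by 0.36 in Q80, 0.29 in Q92, 0.37 in Q111, 0.27 in Q140 and 0.34 in Q175. In Q20, whose repeat is short, the comparison with its wild types asks what the knock-in allele does without expansion. There Abhd1 was at 1.11 at 6 months (SE 0.146, adjusted p = 5.44e-07, 7 of 8) and 1.09 at 10 months (SE 0.187, adjusted p = 0.00494, 8 of 8). Dpysl5 was at 0.27 (adjusted p = 0.00191, 7 of 8) and 0.35 (adjusted p = 0.00494, 8 of 8), and Atraid at -0.21 at 6 months (adjusted p = 0.00164, 7 of 8). At 6 months 4 genes passed (3 higher, 1 lower), with Gm2420 (2.06) as the fourth, and at 10 months 2. At 2 months edgeR gave 0 genes, with 404 at an unadjusted p under 0.05, and DESeq2 1, and Abhd1 stood at 1.14 (adjusted p = 0.278). By the GENCODE M21 annotation (GRCm38), used only to measure distance because the authors' build is not given in the sources used here, all 4 genes called at 6 months and both at 10 months lay within 10 Mb of Htt. Genes in that window made up 0.984% of those tested at 6 months. The medium spiny neuron genes had 0 of 24 members past the threshold in Q20 against wild type at 6 months (median 0.10).

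The effect of Q175 against Q20 was compared between ages by a test of the difference itself. Between 2 and 6 months 1416 genes differed (612 toward higher, 804 toward lower). The 5 with the smallest p were Hrk, a BH3-only cell death gene, at -0.20 at 2 months and -1.31 at 6 months (difference -1.10, SE 0.105), Scn4b (-0.30 and -1.46), Vwa7 (-0.30 and -2.07), Hipk4 (-0.31 and -1.18) and Ddit4l (-0.59 and -1.87). Without the 7 libraries 1839 genes differed, 939 of them shared. Between 6 and 10 months 2 genes differed: Emx2, a homeobox gene of the forebrain, at 0.17 and 0.86 (difference 0.67, SE 0.125) and Gpd1, a glycerol-3-phosphate dehydrogenase, at -0.37 and -0.05. Serpinb1b, Pomt1 and Emx2os followed without passing (adjusted p = 0.061 each). More genes passed in this test without a filter on low counts and with RLE factors, so its count depends on the processing.

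Across genes, which are not independent replicates, the changes of Q175 at 6 and 10 months had a Pearson r of 0.62 and a Spearman rho of 0.64. Of 3158 genes called at both ages 3155 changed the same way. Between 2 and 6 months r was 0.19 and rho 0.17, and all 37 genes called at 2 months had the same sign at 6 months, where 35 of them passed. Between 2 and 10 months r was 0.14 and rho 0.063, and 0.32 and 0.39 without the 7 libraries. Over lines against their own cage mates, changes of Q140 and Q175 correlated across genes with r 0.56 and rho 0.63, and 3441 of 3444 genes called in both had the same direction (1356 would be shared by chance). Q111 and Q175 had r 0.31 and rho 0.43, Q111 and Q140 0.24 and 0.47, and Q20 and Q175 -0.15 and -0.25. In all 15 pairs of lines and 3 pairs of ages were compared.

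The effect of Q175 was also compared between females and males. Within sex, 3495 genes passed in females and 4534 in males at 6 months, 2410 and 1485 at 10 months and 2 and 11 at 2 months. The 2537, 981 and 2 genes called in both sexes at those ages all changed the same way. Over all genes the changes in females and males correlated with r 0.561 at 6 months, 0.451 at 10 months and -0.259 at 2 months. At 2 months Q20 M2 and M3, both male, were among the libraries set apart, and r was computed with all libraries only. Lists that turned with the libraries set apart had female minus male medians of 0.61 (ribosomal protein genes), 0.61 (respiratory chain) and 0.41 (proteasome). The negative r therefore does not show an opposite effect in the sexes. The test of the difference gave 0 genes at each age with edgeR, the only tool run for it, with 993, 727 and 1180 genes at an unadjusted p under 0.05 at 6, 10 and 2 months. The smallest p at 10 months was that of Oxt, the oxytocin precursor, at 2.12 in females and -2.39 in males (difference 4.51, adjusted p = 0.967), and at 2 months that of Ddx41 (-0.17 and 0.29, adjusted p = 0.463). At 6 months Ppil2 (0.08 and -0.11), Upp1 (0.30 and -0.65) and Wnt7a (-0.50 and -0.06) came first (adjusted p = 0.689 each). In simulated data of that age the sex test found 56.7% of log2 differences of 0.5 and 78.8% of those of 1. The counts of 0 therefore do not show that the sexes respond alike.

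The 6 wild-type groups of 6 months, which share a genotype and differ in the line they were housed with, were compared as a check on the cohorts. There were 222 genes that differed among them, led by ENSMUSG00000078821, Macf1, Usf3, Atp5j2 and Ubap2l. Macf1, a cytoskeletal linker, was highest in the wild types housed with Q111, at 487 ± 13.4 CPM (SD, n = 8). Atp5j2, an ATP synthase subunit, was at 76.6 ± 2.98 CPM in those housed with Q92 and between 69.5 and 71.1 in the others. Of 9 choroid plexus and ependymal markers 4 differed, of 79 respiratory chain subunits 11, and of the 24 medium spiny neuron genes 1.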

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

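The test of depth for the 7 libraries of 2 months, the test of Q92 against the wild types of its cohort, the use of the correlation with length for the medium spiny neuron genes, the fits with tissue scores as covariates and the fits without single libraries were chosen only after the result was seen.

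In Q175 at 6 months 23 of 24 medium spiny neuron genes were lower than in Q20, with a median of -0.62. A lower share of these neurons in the tissue would raise the markers of all other cell types alike. The median of the endothelial and mural markers was -0.201 (SE 0.0344), which for these markers argues against a lower share as the whole cause. Oligodendrocyte genes stood at -0.156 (SE 0.0662) and microglia markers at -0.0504 (SE 0.0192). Astrocyte (-0.0484, SE 0.0554), interneuron (-0.0887, SE 0.142) and precursor markers (0.135, SE 0.0851) did not decide. The SE takes the genes of a list as independent. With scores of cortical, thalamic and choroid plexus tissue as covariates the median was -0.507, and the log2 changes of 17372 genes correlated with exonic length with a rho of -0.00631, so neither more of these tissues nor a length bias accounts for it as a whole. A lower level of these transcripts within the neurons may account for the pattern, a hypothesis drawn from the same data and not itself tested. A partial loss of neurons together with changes in other cell types stays open as untested.

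The 7 libraries of 2 months with a median correlation under 0.97 lay in 5 groups and both sexes, so no biological explanation was tested. Lower depth is argued against, since 7 of the 7 had a total at or above the median of their age. Tissue other than striatum is argued against too, since 0 of the 7 lay above the highest other library in the cortical, thalamic or choroid plexus score. A bias by transcript length is consistent with their deviations, which correlated with exonic length across 13207 genes with a rho of -0.655 to -0.592, against -0.598 to 0.429 in the 49 others. What brought the bias about was not tested, and Q140 F4 and Q175 F4 (lowest median correlation of its group) reached a similar rho without standing apart.

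Q92 differed from Q20 in 1056 genes at 6 months but from its own wild-type cage mates in 9. Across the genes called in Q92 against Q20, the difference between the wild types housed with Q92 and those housed with Q20 correlated with r 0.735 and rho 0.663 (r 0.140 over all genes), which for the called genes is consistent with a difference between cohorts that wild types share. With the tissue scores as covariates 253 genes passed, and 8 of 12 cortical markers were higher, so cortical tissue in some Q92 samples may add to it. For Q80, Q111, Q140 and Q175 the same correlation was 0.984, 0.289, -0.106 and -0.196 over called genes and 0.325, 0.0624, -0.0218 and -0.0784 over all. The value of Q80 over called genes rests on 51 genes led by choroid plexus genes, and without the library Q80 F3 0 genes passed. Q80 F3 and the wild type M2 housed with Q80 had the highest choroid plexus scores, so that value need not reflect a difference of whole cohorts. An effect of the Q92 allele in addition stays open, with 9 genes against cage mates and 0 once the same difference of Q20 was taken off.

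Each of 8 measures was tested in the 26 groups for a library far from the other 7 of its group, and 34 of these tests found one, where chance gives about 1 in 20. Total counts stood apart in Q20 M1 at 6 months (39685629, lowest), in wild type M3 housed with Q20 at 2 months (34766393, highest) and in wild type F3 housed with Q92 at 6 months (41734097, highest). The median correlation with the age was lowest in Q80 M5 (0.872), Q111 F2 (0.968), wild type F1 (0.968) and Q175 F4 (0.984) at 2 months, in Q80 F3 (0.979) and Q140 M2 (0.987) at 6 months, and in wild type F3 (0.984) and Q140 F1 (0.987) at 10 months. Mitochondrial counts were highest in Q80 M5 (24.1%), Q111 F2 (17.4%) and wild type F1 (17.2%) at 2 months and lowest in Q111 M2 (10.6%) at 6 months. Htt in log2 CPM was lowest of its group in Q80 M5 (6.22), wild type F1 (6.64), Q111 F2 (6.72) and Q140 F4 (6.83) at 2 months. The same held for Q175 F2 at 6 months (7.13) and for Q175 M4 (6.39), Q140 F1 (6.64) and wild type F3 (6.77) at 10 months.

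The cortical score was highest of its group in Q92 F2 (2.80) and Q20 M3 (1.14) at 6 months and in Q111 M3 (1.17) at 10 months. The thalamic score was highest in Q92 M1 (1.69), Q140 M2 (1.32) and Q80 F3 (1.22) at 6 months and lowest in wild type F2 at 10 months (-0.846). The choroid plexus score was highest in Q80 F3 (5.02), in wild type M2 housed with Q80 (5.02) and in wild type F3 housed with Q175 (0.417) at 6 months and in Q20 F5 at 10 months (0.716).

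Differences of the Q175 effect between ages were found by their own test. Between 6 and 2 months 1416 genes differed, among them Hrk (-1.10), Scn4b (-1.16), Vwa7 (-1.76), Hipk4 (-0.87) and Ddit4l (-1.28). Between 10 and 6 months 2 genes differed, Emx2 (0.67) and Gpd1 (0.31).

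Labels were shuffled within sex in 100 splits, or within sex and age in 50 for the age tests. Chance was called excluded where fewer than 5 in 100 gave as many genes, with no allowance for the number of tests. Against Q20 it was excluded for Q175 at 2 months (37 genes, highest other split 0), 6 months (6382, 1673) and 10 months (4212, 372), for Q140 (4925, 1504) and Q111 (2261, 162) at 6 months and for Q140 (3870, 32) and Q111 (2143, 131) at 10 months. It was also excluded for Q92 at 6 months (1056, more than in any other split). At 10 months Q92 (192, 209, with 2 splits as large) and Q80 (21, 415, with 3 splits as large) met the rule. Other splits there called more genes than the real grouping, so the shuffles do not settle these. Chance was not excluded for Q80 at 2 months (2 genes, 29 splits as large, highest 5498) and 6 months (51, 5 splits) or for Q111 at 2 months (3, 8 splits). Against cage mates chance was excluded for Q111 (1577, 263), Q140 (4263, more than in any other split) and Q175 (5612, 1929) but not for Q80 (9, 60 splits as large) or Q92 (9, 7 splits, highest 197). For Q20 against wild type it was excluded at 6 months (4, highest 2) and not at 10 months (2, 18 splits, highest 8). It was excluded for the trends at 6 months (6931, 106) and 10 months (5608, 884) and for the wild types by housing (222, 27). Shuffles of single libraries break up the lines and cohorts. A real count above them shows a difference between groups from any cause, a cohort included. For the trends they therefore do not test a link to repeat length itself. The trend at 2 months met the rule (60, 4 splits as large), but other splits called up to 6495 genes, so the shuffles do not settle it. The shuffles of the age and sex tests remove the Q175 effect in each age or sex, so they cannot test whether it is the same. From 2 to 6 months 1416 genes stood against 856 in the highest other split. From 6 to 10 months 2 genes stood against 1196, with 9 of 50 splits as large. A count of 0 is reached by all 100 splits whatever the data, so they decide nothing at 2 months for Q92 and Q140 against Q20 and for Q20 against wild type (highest 7845, 0 and 2) or for the sex differences at 2, 6 and 10 months (highest 39, 6376 and 3656). Where other splits called many times the real count, as with 5498, 6495 or 7845 genes at 2 months, they point to a structure of the samples, and at that age the 7 libraries set apart form one.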

How the results depend on the processing

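The fits without the 7 libraries, with tissue scores as covariates, less the difference of Q20 from its cage mates, without the library lacking Y-linked counts and without single libraries were chosen after the data were seen, and all other alternatives before. Of 1431 values of named genes under the alternatives with all or most libraries, 1208 kept their direction and side of the threshold, 216 kept their direction but no longer passed, 2 came to pass and 5 reversed. The counts of Q111, Q140 and Q175 against Q20 at 6 and 10 months stayed within 1.5 times their value under DESeq2, RLE factors, no filter, the replicate block, the L code, the groups compared alone, wild types as the reference, tissue scores and FPKM. On FPKM, however, 75.7% of the genes called in Q175 at 6 months and 77.0% at 10 months were higher, where the medians of all genes lay at 0.05 on the log2 scale. RLE factors kept the sign of all 29 list medians in Q175 at the 3 ages. With 8 libraries per group, simulated changes were found less often the smaller they were, so a count of 0 does not show that small changes are absent. In Q175 against Q20 simulated log2 changes of 0.3 were found in 35.8% of genes at 2 months, 65.7% at 6 months and 67.2% at 10 months. For the age difference from 2 to 6 months the share was 19.4% at 0.3 and 53.7% at 0.5. Where no cause is given below, the cause was not tested.

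With a minimum absolute log2 change of 0.3, which leaves fewer genes by construction, the 6 month counts were 205 (Q92), 612 (Q111), 1483 (Q140) and 2192 (Q175), and those of 10 months 5 (Q80), 90 (Q92), 861 (Q111), 1398 (Q140) and 1605 (Q175). With DESeq2 the counts were 11 (Q140) and 65 (Q175) at 2 months, 353 (Q80) at 10 months, and 1, 7 and 4 for Q20 against wild type at 2, 6 and 10 months. With limma on FPKM they were 1 (Q80), 4 (Q140) and 22 (Q175) at 2 months and 3 (Q80) at 6 months. Without a filter they were 1 (Q80) and 1 (Q111) at 2 months, 1 (Q80) at 10 months and 5 for the age difference from 6 to 10 months, which was 7 with RLE factors.

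With only the groups compared, and so fewer libraries in the fit, the counts were 1 (Q80), 0 (Q111) and 11 (Q175) at 2 months, 0 (Q80) and 100 (Q92) at 6 months and 0 (Q80) and 54 (Q92) at 10 months. With wild types as the reference they were 4 (Q80), 66 (Q111), 12 (Q140) and 79 (Q175) at 2 months, 9 (Q80) and 9 (Q92) at 6 months and 298 (Q92) at 10 months, and Cplx3 in Q111 at 6 months turned to -0.092. With the replicate block they were 1 (Q80) and 0 (Q111) at 2 months, 17 (Q80) at 6 months and 5 (Q80) at 10 months, and Atp6v0c-ps2 in Q80 at 2 months turned to -0.30 (-0.295). At 6 months the replicate block gave 2655 (Q111), 5478 (Q140) and 6874 (Q175), and there 36 of 48 female and 31 of 48 male libraries correlated best with those of their own number in other groups (mean r 0.181 and 0.109, lowest -0.304 and -0.342), a hint from the data and not the design. At 2 months 6 of 27 and 1 of 29 did so, and at 10 months 5 of 29 and 12 of 27. With the L code they were 0 (Q80), 0 (Q111) and 24 (Q175) at 2 months, 0 (Q80) at 6 months and 1172 (Q80) and 102 (Q92) at 10 months.

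With tissue scores as covariates the counts were 0 (Q80), 0 (Q111) and 66 (Q175) at 2 months, 1 (Q80) and 253 (Q92) at 6 months, 68 (Q80) and 442 (Q92) at 10 months, 29 for Q92 against cage mates and 94 for the trend at 2 months. Slc4a5 in Q80 (-0.018), Igfn1 in Q92 (-0.22) and Tcf7l2 in Q111 against cage mates (0.040) reversed with them. Without the 7 libraries the counts at 2 months were 1 (Q80), 0 (Q111), 2 (Q140), 84 (Q175) and 255 (trend), and r between the changes at 2 and 10 months was 0.32. Less the difference of Q20 from its cage mates, the 6 month counts were 0 (Q80), 0 (Q92), 540 (Q111), 2673 (Q140) and 4151 (Q175). The trend at 2 months had 103 genes with the rank of the line, 196 without Q20 and 0 without Q175, and the trend at 6 months 4285 without Q175. Over called genes alone r was 0.81 for Q140 and Q175, 0.46, 0.82 and 0.43 for 2 and 6, 6 and 10, and 2 and 10 months, as these genes were chosen for their change. With an estimated correlation the list tests that passed at the 3 ages together went from 28 to 7.

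Without single libraries the counts were 0 for Q80 against Q20 without Q80 F3, 5.1e+02 (rounded to 2 digits) for Q92 against Q20 without Q92 F2, and from 5 to 58 for Q80 against cage mates, and the trend at 2 months had 100 genes without Q20 F4. Without Q20 M4, which held most of their Q20 counts, Gh turned to 0.26 in Q140, 0.60 in Q175 and 0.032 in the 6 month trend, and Prl to 0.16, 0.10 and 0.019. Prl in Q140 against cage mates turned to 1.27 without the wild type F2.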

Other observations

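Several lists that did not pass in Q175 had single members that changed. Their tests were set before the data were examined, and the single members named were chosen only after their values were seen. Among 14 mismatch repair genes Mlh3 (0.15), Lig1 (0.22) and Pcna (0.09) rose at 6 months, and at 10 months Msh3 (0.20), Mlh3 (0.19) and Pcna (0.20) rose; these genes act on repeat instability, and the list did not pass (adjusted p = 0.0995 and 0.061). Myelin genes moved apart: Mobp fell by 0.40 and Mal by 0.37 at 10 months while Cnp rose by 0.15 and Mog by 0.20, with 6 lower and 2 higher of 12 (adjusted p = 0.065). Precursor genes of the same lineage were higher at 6 months, Olig2 by 0.38 and Olig1 by 0.33, 3 of 6 in all (adjusted p = 0.172). Of 22 cholesterol synthesis genes 8 fell and 2 rose at 6 months, with Insig1 and Msmo1 at -0.38 each and Mvk at 0.22 (adjusted p = 0.111), and the median of -0.074 kept its sign under each scaling. Insig1 lies within 10 Mb of Htt and stood at -0.264 in Q140 and -0.295 in Q175 against cage mates. Its fall need not reflect the pathway, since an effect of its place near the altered allele was not tested.

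Synaptic vesicle genes split at 6 months, with Syp at 0.41, Syn1 at 0.23 and Sv2a at 0.17 higher and Cplx2 at -0.35 lower, 5 and 2 of 16 (adjusted p = 0.245). The astrocyte genes S100b (0.31) and Slc1a2 (-0.33) also moved apart. Of the p53 targets Sesn2 rose by 0.21 while Plk2 (-0.44) and Cdkn1a (-0.47) fell, so that a median of 0.041 stood beside a test pointing down (adjusted p = 0.802). Among chaperones Hspa8 rose by 0.15 and Dnajb4 fell by 0.20, and among 81 ribosomal protein genes 4 rose and 8 fell (2 and 4 adjusted over the list alone, adjusted p = 0.335). Calb2, a calretinin interneuron gene, rose by 0.89 while 4 other interneuron markers fell (adjusted p = 0.258). Thalamic, cortical, choroid plexus and blood lists did not pass in Q175 at 6 months, with medians of 0.54, 0.31, 0.24 and -0.27 and 0, 1, 0 and 0 members called.

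The prediction for genes near Htt was written before its test was run. A donor segment of another strain around the knock-in allele is a candidate explanation for the calls of Q20 against wild type, since embryonic stem cells used for knock-ins often come from another strain than the one they are bred to. Among genes with an unadjusted p under 0.001, the share within 10 Mb of Htt was 34.3, 36.3 and 22.2 times their share of tested genes at 2, 6 and 10 months. At 2 months the ratio rested on 1 of 3 such genes, against 5 of 14 at 6 months and 5 of 23 at 10 months. The ratio was 31.3 in Q80 and 16.9 in Q92 against cage mates, with 4 of 8 and 5 of 9 calls other than Htt in the window, and it was 1.15 in Q111 (Fisher exact p = 0.359), 1.78 in Q140 (p = 7.14e-05) and 1.47 in Q175 (p = 0.00161), where changes elsewhere in the genome were far more numerous. An effect of the inserted allele on its neighbours could give the same excess and was not told apart here, because the design holds no line with the segment alone.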
